A study of Petunia x hybrida with 8 samples.

How the data were processed

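RNA was sequenced from corolla, the ring of petals, of Petunia x hybrida in 6 libraries, 3 of wild type and 3 named odo1i. ODO1 (ODORANT1) is an R2R3-MYB transcription factor known as a regulator of floral scent in petunia, and odo1i is read here as plants in which ODO1 was silenced, which the labels do not spell out. Corolla chromatin was also immunoprecipitated with an antibody against GFP in 2 libraries, 1 named pODO1 and 1 named 35S. The 35S promoter is a strong plant virus promoter. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

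The RNA libraries were primed with oligo-dT, per the labels. The authors deposited whole-number read counts per gene ID without normalization. The submitters' processing notes name cutadapt, TopHat2, HTSeq, DESeq2, Bowtie2 and MACS2, with no versions or roles. Aligner settings, annotation release and use of strand in counting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore not be told apart. Scaffold and gene names begin with Peaxi162, and the genome build is not otherwise given in the sources used here. All 6 columns of the count table were matched to samples by name. The table lists 35812 IDs, of which 12169 had 0 counts in every library. The 35812 IDs include 2884 written with a t in place of a g, which held 0.000749% of all counts.

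For each ChIP construct there is 1 peak list, in the 10-column layout that MACS2 writes, without a header. The lists are tied to the constructs by the names they were deposited under, which also contain ODO1. The fold enrichment of a peak is the authors' deposited ratio, read as enrichment over the peak caller's local background. The −log10 q of each peak is likewise the authors' deposited value, and the lowest in each list is 1.30. The deposited summit offset, in bases from the peak start, is the other value used. Caller settings, effective genome size and the control are not given in the sources used here. The lists do not show whether libraries were pooled for peak calling, and the labels name 1 library per construct. Positions are counted from 1.

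The files do not pair IDs with gene names, and no genome or annotation was used here. The level of ODO1 itself, 16 gene lists fixed by gene name, and the overlap of genes near a peak with changed genes were therefore not analysed here. GC content and gene length were not checked for the same reason.

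Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes of low counts were removed with filterByExpr, which kept 17667, libraries were scaled by TMM, and the groups were compared with the two-sided quasi-likelihood test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Levels are in CPM, the counts of a gene relative to the TMM-scaled total of its library, and the standard error of a log2 fold change is its size divided by the square root of F. A gene with 0 counts in a group was given a bound from a floor of 3 counts over that group. Floors and intervals cover counting error only. Within-group pairs of libraries differed by more than sampling noise, with a chi-square of 26.4 to 151.7 per degree of freedom. The test was first tested on simulated counts for this comparison, drawn for 17667 genes with the means and library sizes of these libraries. Dispersions followed the fitted trend with expression, genes were drawn independently, and no library was made to stand apart. Of 50 changed genes per size the test found 9 at 2-fold, 35 at 4-fold, 48 at 8-fold and 49 at 16-fold, with 5 false calls among 146. Recovery and false calls may differ in the real libraries, which are less even than the simulated ones.

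Peak lists were handled with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and bedtools 2.31.1, and plots were drawn with matplotlib 3.10.9. A peak counted as shared when at least 1 base overlapped a peak of the other list. The chance level came from 100 draws that moved the peaks of one list at random within their scaffolds, with the last peak end in either list taken as the end of the scaffold. Shares have 95% Wilson intervals. Each construct has 1 library, so the peak lists have no replicate check.

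The test of changed genes, the overlap of the peak lists, their alternatives and the rule for named items were chosen before the data were examined. The grouping of called genes on scaffolds, the comparison of single libraries and the deciles of fold enrichment were added later. Because IDs carry no names, the rule gives the 2 IDs with the largest rise and the 2 with the largest fall by log2 fold change, among called genes that average at least 1 CPM and whose groups do not overlap. For peaks it gives the 5 of highest fold enrichment per list and the 5 shared peaks of highest mean fold enrichment. Alternatives were RLE size factors, no filter or a CPM filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, a 2-fold minimum, each library left out in turn, stricter peak thresholds and other overlap rules. Library quality weights in limma-voom and restrictions to long or gene-bearing scaffolds were added after the data were seen.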

Results

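The data comprised read counts for 35812 gene IDs in 6 corolla RNA libraries and 2 peak lists from anti-GFP ChIP of corolla chromatin. Wild type replicates 1, 2 and 4 held 20591367, 19542664 and 18612881 counts, and odo1i replicates 1, 2 and 4 held 18841324, 20034220 and 19669253. The pODO1 list held 98009 peaks and the 35S list 103755. The RNA libraries address which transcripts differ in odo1i corolla, and the peak lists address where a GFP-carrying protein, taken from the names of the lists to be ODO1, was recovered on the genome.

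In odo1i corolla 66 genes were higher and 45 were lower than in wild type, among 17667 tested. The genes that rose went from a median of 19.1 CPM in wild type to 72.1 CPM in odo1i, with a median log2 fold change of 1.97. The genes that fell went from a median of 37.0 CPM to 9.0 CPM, with a median log2 fold change of -2.17, which is unchanged when the 1 called gene with 0 counts in odo1i is set to its bound. Changes of at least 4-fold were found in 33 of the genes that rose and 25 of those that fell, and 106 of the 111 called genes changed at least 2-fold. Among the genes that rose, 23 averaged at least 100 CPM in odo1i, and among those that fell, 6 averaged at least 100 CPM in wild type. In 3 of the genes that fell the odo1i mean was under 0.2 CPM, while no gene that rose had a wild type mean under 0.2 CPM. Calls were made with the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 3 libraries per group. The level of ODO1 was not analysed here, so the odo1i label was not checked against its target.

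The number of called genes depended on single libraries, on the filter, on the tool and on whether the replicate number was used as a block. Without wild type replicate 4 it was 435 (237 higher, 198 lower), and all 111 genes were among them with the same direction. It was 3 without wild type replicate 1, 21 without wild type replicate 2, 4 without odo1i replicate 1 and 10 without odo1i replicate 4. Without odo1i replicate 2 edgeR called 0 genes, with 1673 at an unadjusted p under 0.05. With all libraries, edgeR without a low-count filter called 179 genes (109 higher, 70 lower), DESeq2 1133 (527 higher, 606 lower) and limma-voom with library quality weights 1122 (586 higher, 536 lower), each with all 111 among them. Limma-voom without weights called 117 genes (70 higher, 47 lower), with only 94 of the 111 among them. With the replicate number as a block edgeR called 194 genes (104 higher, 90 lower), with only 92 of the 111 among them.

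**Figure D1:**
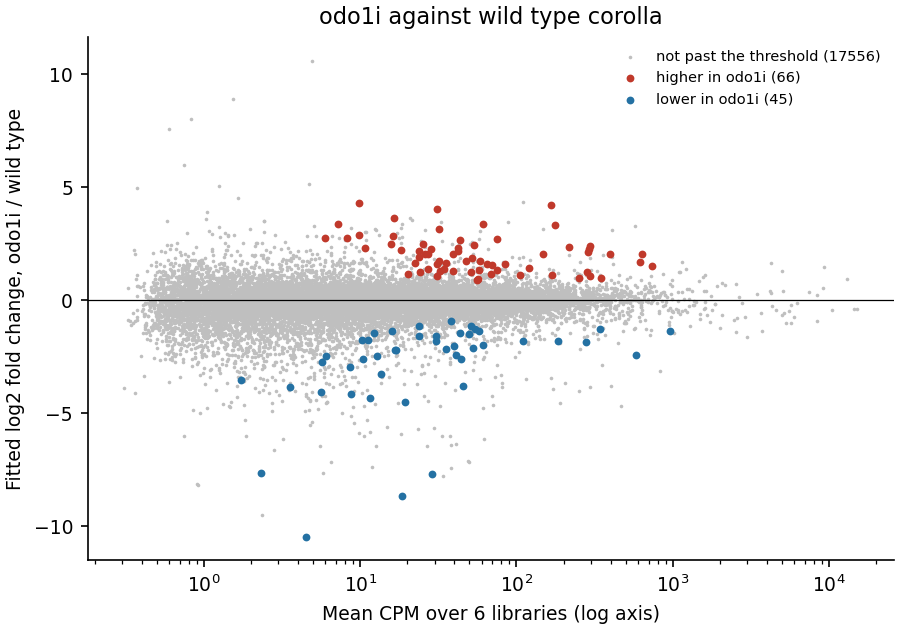
Each point is 1 of 17667 tested genes, with its mean CPM over the 6 libraries on a log axis and its fitted log2 fold change of odo1i over wild type on the vertical axis. The 66 called genes higher in odo1i are red and the 45 lower are blue, and grey points did not pass an adjusted p of 0.05.

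The 2 called genes with the largest rise by the fixed rule were Peaxi162Scf00408g00225 and Peaxi162Scf00049g02410, whose order turned when wild type replicate 1, wild type replicate 4 or odo1i replicate 1 was left out. Peaxi162Scf00408g00225 went from 0.961 ± 0.795 CPM in wild type to 18.6 ± 3.78 CPM in odo1i (SD, n = 3 each). Its log2 fold change was 4.28 ± 0.60 (SE), with an edgeR adjusted p of 0.0456. Wild type replicate 2 held 34 of its 54 wild type counts, and without that library its log2 fold change was 5.18; in limma-voom with quality weights it was 4.92. Peaxi162Scf00049g02410 rose from 17.0 ± 2.90 CPM to 314.9 ± 105.5 CPM (SD, n = 3 each), with a log2 fold change of 4.21 ± 0.31 (SE) and an edgeR adjusted p of 0.00747. Its lowest odo1i library held 195.1 CPM and its highest wild type library 20.3 CPM.

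The 2 called genes with the largest fitted fall kept almost no reads in odo1i. Peaxi162Scf00968g00018 had 512 counts over the 3 wild type libraries and 0 over the 3 odo1i libraries. From a wild type mean of 9.04 ± 4.68 CPM (SD, n = 3) it was at least 179-fold lower in odo1i, against a floor of 3 counts over the group, or 0.0506 CPM (edgeR adjusted p = 0.0456). With 1 library left out this bound ran from 117-fold, without odo1i replicate 4, to 232-fold, without wild type replicate 1, and was 119-fold without odo1i replicate 2. Peaxi162Scf01226g00004 fell from 36.8 ± 7.69 CPM to 0.0813 ± 0.141 CPM (SD, n = 3 each), and its 5 counts in odo1i all came from replicate 4. Its log2 fold change was -8.67 ± 0.75 (SE), with an edgeR adjusted p of 0.0124, and this size rests on that library. Without odo1i replicate 4 the odo1i group had 0 counts and the gene was at least 477-fold lower, while limma-voom gave a log2 fold change of -9.34, and -9.65 with quality weights.

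Each of these 4 genes kept its direction but lost its call when wild type replicate 1 was left out, with edgeR adjusted p from 0.0548 to 0.0936, and when odo1i replicate 2 was left out, with edgeR adjusted p from 0.0715 to 0.240. Over all alternatives their adjusted p ran from 4.79e-40 to 0.240. Peaxi162Scf00408g00225 also lost its call without odo1i replicate 1 (edgeR adjusted p = 0.0924) or 4 (0.184), and Peaxi162Scf01226g00004 without odo1i replicate 1 (edgeR adjusted p = 0.0543). Peaxi162Scf00968g00018 also lost it without wild type replicate 2 (edgeR adjusted p = 0.0932), odo1i replicate 1 (0.0879) or odo1i replicate 4 (0.138), and in limma-voom (adjusted p = 0.0986).

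**Figure D2:**
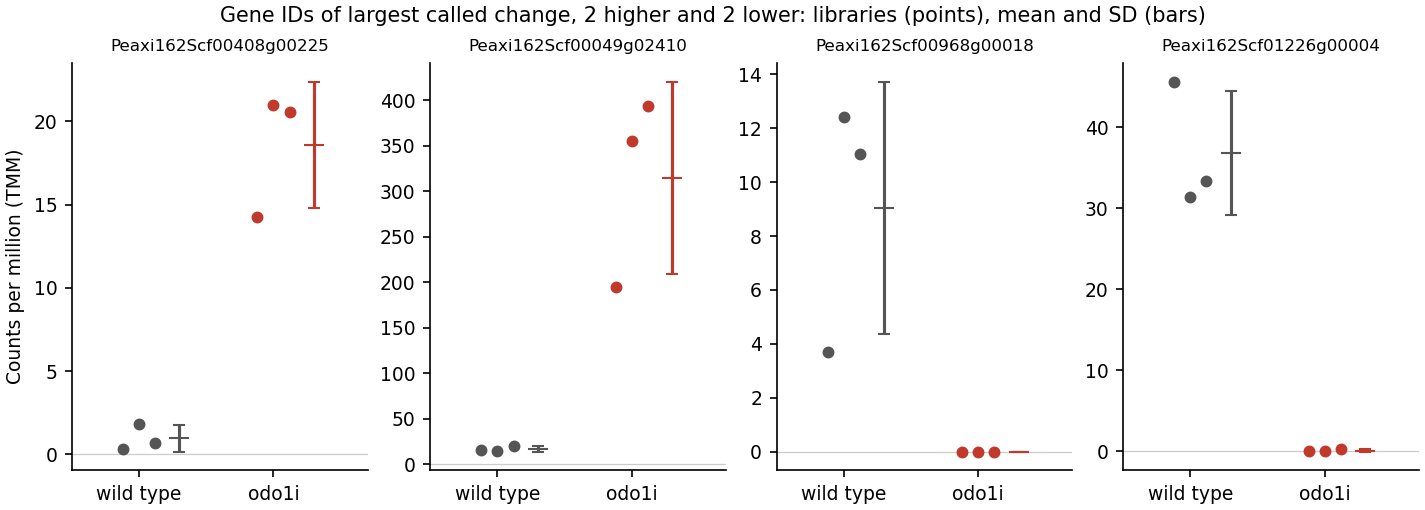
Each panel gives 1 gene ID, with TMM-scaled CPM on the vertical axis, 1 point per library, and the mean with SD beside the points. Peaxi162Scf00049g02410 lies between 195.1 and 394.2 CPM in odo1i, and Peaxi162Scf00968g00018 has 0 counts in all 3 odo1i libraries.

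The groups did not overlap in CPM at any of the 111 called genes, which the call itself nearly forces with 3 libraries per group. They also did not overlap at 22.5% of all tested genes, against the 10% that chance gives on average for 3 against 3. At an unadjusted p under 0.05 there were 2695 genes, where chance gives 883 on average. Genes vary together across libraries, so a single split can lie far from these averages, and neither excess was tested. When the tested genes were divided by mean expression into 3 equal classes, 67 called genes lay in the highest class (median 66.6 CPM), 36 in the middle class (14.5 CPM) and 8 in the lowest (2.25 CPM).

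The called genes lay on 96 scaffolds, of which 11 carried more than 1. Peaxi162Scf00408 carried 4 called genes among its 34 tested genes, and all 4 were higher in odo1i. This scaffold was singled out after its values were seen. Called genes formed 20 pairs on a common scaffold, against a mean of 13.2 in 100000 random sets of tested genes (permutation test, one-sided p = 0.0857). Called genes next to each other in ID order numbered 2, against a mean of 0.639 (permutation test, one-sided p = 0.135). Neither number passed 0.05.

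Wild type replicate 4 differed from the other libraries. At 1217 genes it was over 2-fold above every other library, on the log2(CPM + 1) scale, where each of the other libraries had 6 to 134 such genes. Its Spearman correlations with the other libraries, across genes, were 0.894 to 0.916, while those among the other 5 libraries were 0.934 to 0.976. None of its 1217 raised genes was among the 111 genes that edgeR called. The choice of these genes nearly forces this, as each varies widely within wild type. It does not show that this library leaves the calls untouched.

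**Figure D3:**
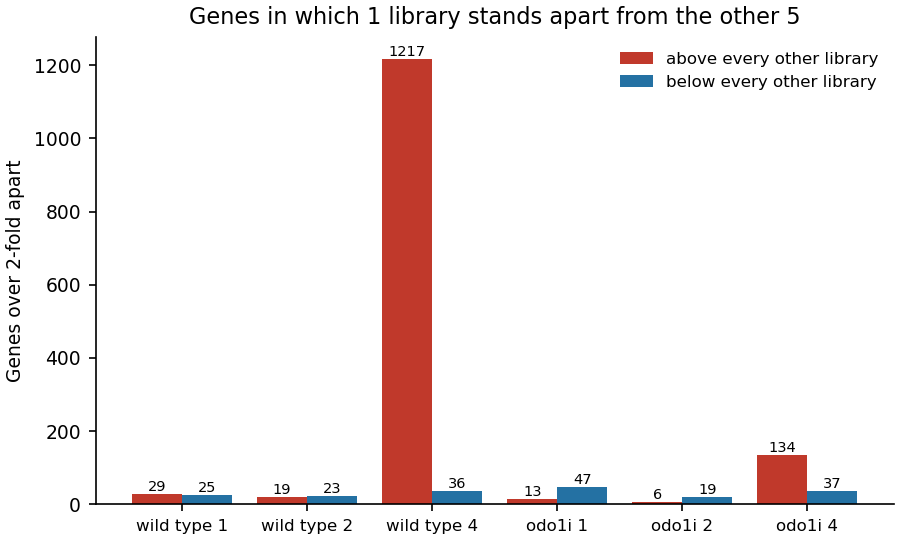
Bars count, for each of the 6 RNA libraries on the horizontal axis, the genes over 2-fold above (red) or below (blue) every other library, on the log2(CPM + 1) scale. Wild type replicate 4 has 1217 genes above, and odo1i replicate 4 follows with 134.

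Peaks of the pODO1 list lay on 7032 scaffolds and those of the 35S list on 7873. They were short, with a median width of 133 bases for pODO1 and 128 bases for 35S, and covered 15476 and 15776 kb. The authors' fold enrichment had a median of 4.28 in the pODO1 list (quartiles 3.63 and 5.05) and 3.70 in the 35S list (quartiles 3.13 and 4.36). It reached 10-fold at 231 pODO1 peaks and 101 35S peaks. A −log10 q of at least 5 was reached by 37989 pODO1 and 35350 35S peaks. At a fold enrichment of at least 4 there were 58371 and 37141, and with both minimums 34318 and 27772. A higher fold enrichment in one list than in the other was not read as a difference between the constructs, since the depths of the ChIP and control libraries are unknown.

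The highest fold enrichment in the pODO1 list, 23.97, was at positions 970279 to 970621 of Peaxi162Scf00384. It was followed by 762 to 890 of Peaxi162Scf43430 (20.3), 352859 to 352998 of Peaxi162Scf01111 (20.2), 174097 to 174225 of Peaxi162Scf00767 (20.1) and 342000 to 342153 of Peaxi162Scf00163 (17.7). In the 35S list the highest was at 1531770 to 1532499 of Peaxi162Scf00047 (19.5). It was followed by 2800482 to 2800619 of Peaxi162Scf00016 (17.8), 696553 to 698366 of Peaxi162Scf00488 (17.6), 1532782 to 1533160 of Peaxi162Scf00047 (17.3) and 1527835 to 1529084 of Peaxi162Scf00207 (15.6). Each of these 10 peaks overlapped a peak of the other list. The 35S peaks on Peaxi162Scf00488 and Peaxi162Scf00207 span 1814 and 1250 bases. They belong to the wide peaks, treated under other observations, for which ChIP background and binding cannot be told apart. Whether they lie in promoters, exons or introns was not analysed here.

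Many sites were found with both constructs. Of the pODO1 peaks 44007 (44.9%, 95% Wilson interval 44.6 to 45.2) overlapped a 35S peak, and of the 35S peaks 44146 (42.5%, 42.2 to 42.8) overlapped a pODO1 peak. Peaks placed at random within their scaffolds overlapped in 5.72% ± 0.051 and 5.43% ± 0.053 (SD over 100 draws), and the observed shares were 7.85 and 7.83 times as high. On scaffolds spanning at least 100000 bases, a restriction added after the data were seen, random placement gave 2.81% and 2.65%, and the observed 43.3% and 41.2% were 15.4 and 15.5 times as high. With a fold enrichment of at least 4 required in both lists the shares were 26.1% of pODO1 and 40.9% of 35S peaks. How much of the overlap is background common to both libraries is unknown, as the control is not given.

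The strongest peaks were shared most often. In the highest decile of fold enrichment 73.0% of pODO1 peaks were shared, against 34.3% in the lowest decile. Among 35S peaks 64.2% of the highest decile were shared, 34.8% to 48.6% of the deciles between, and 47.9% of the lowest. Of the peaks enriched at least 10-fold, 221 of 231 pODO1 and 95 of 101 35S peaks were shared. In the 44497 overlapping pairs the summits lay a median of 27 bases apart, and 85.1% were within 100 bases.

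**Figure D4:**
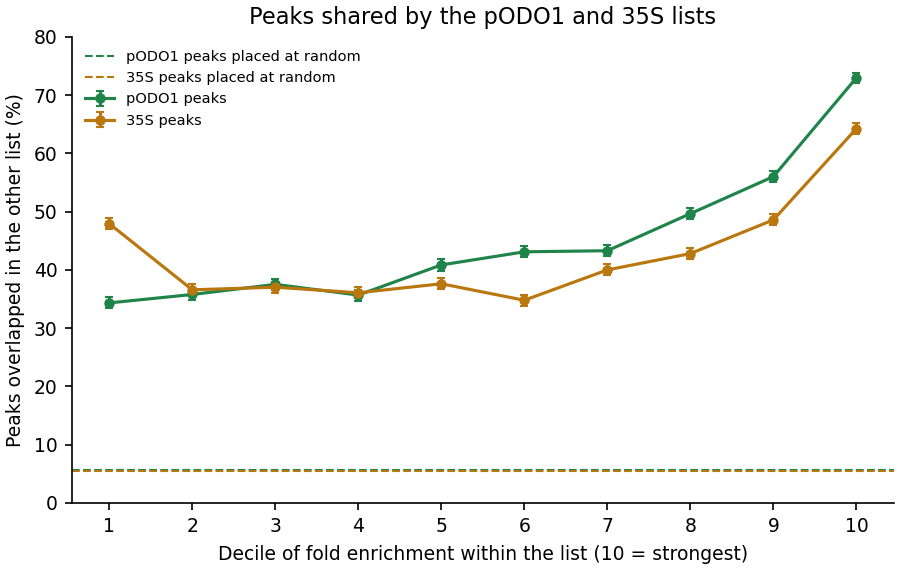
The percentage of peaks overlapped by at least 1 base in the other list is plotted for deciles of fold enrichment within each list, from weakest (1) to strongest (10), with 95% Wilson intervals. Sharing reaches 73.0% of pODO1 and 64.2% of 35S peaks in the highest decile. The dashed lines mark randomly placed peaks of each whole list, at 5.72% and 5.43%, and not the chance level of single deciles.

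The shared site of highest mean fold enrichment was that on Peaxi162Scf00384, with 23.97-fold in the pODO1 list, 14.5-fold in the 35S list and summits 7 bases apart. Next came 762 to 890 of Peaxi162Scf43430 (20.3-fold and 15.6-fold) and 174097 to 174225 of Peaxi162Scf00767 (20.1-fold and 15.5-fold). They were followed by 2800473 to 2800628 of Peaxi162Scf00016 (16.3-fold and 17.8-fold) and 342000 to 342153 of Peaxi162Scf00163 (17.7-fold and 14.7-fold), with positions from the pODO1 list. The summits at these 4 sites differed by at most 6 bases between the lists. Peaxi162Scf43430 carries no gene ID of the count table, and its last peak ends at position 890.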

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

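The tests with library quality weights and on long or gene-bearing scaffolds were chosen after the results were seen. Against 111 genes called by edgeR, RLE size factors, a CPM filter, limma-voom and a 2-fold minimum called 106 to 142. Of the 111 genes, RLE size factors kept 110, the CPM filter 111, limma-voom 94 and the 2-fold minimum 106. Without a filter 179 were called (109 higher, 70 lower), by DESeq2 1133 (527 higher, 606 lower, with 786 adjusted p not given) and with quality weights in limma-voom 1122 (586 higher, 536 lower). The 111 genes were among the calls of these last 3, with the same direction. The quality weights were 0.239 for wild type replicate 4 and 0.808 to 2.45 for the other libraries, so that fit counts this library least. The cause of the higher numbers was not tested. Leaving out 1 library gave 0 to 435 calls, and only the fit without wild type replicate 4 gave more than 111. Fewer libraries per group by construction lower the power of the others. With the replicate number as a replicate block 194 genes were called (104 higher, 90 lower), 92 of them among the 111. Same-numbered libraries of the groups deviated from their group means with correlations of 0.189, 0.0977 and 0.115, 1 of them under the 0.1 required to treat them as paired. All 6 libraries correlated best with their own number, and no correlation with another number exceeded -0.0152. These 6 results are not independent, as deviations from a group mean sum to 0. Both groups also carry the same numbers 1, 2 and 4, but the labels do not say what they mark. Pairing was therefore neither shown nor excluded. The 4 named genes kept their direction under 13 alternatives each, and 4, 2, 6 and 3 of these ended the call of Peaxi162Scf00408g00225, Peaxi162Scf00049g02410, Peaxi162Scf00968g00018 and Peaxi162Scf01226g00004.

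A −log10 q of at least 5 left 37989 pODO1 and 35350 35S peaks, a fold enrichment of at least 4 left 58371 and 37141, and both left 34318 and 27772. The percentages of pODO1 and 35S peaks shared were 42.6 and 40.3 with an overlap of at least 0.5 of the shorter peak, 38.7 and 36.6 with summits within 100 bases, 38.6 and 41.5 with a −log10 q of at least 5, and 26.1 and 40.9 with a fold enrichment of at least 4. On scaffolds spanning at least 100000 bases they were 43.3 and 41.2, against 2.81 and 2.65 at random, and on scaffolds with a gene ID 43.3 and 41.1. The 26.1 and 40.9 differ because a similar number of shared peaks is divided by 58371 pODO1 and 37141 35S peaks. The cause of the shifts from the main shares was not tested. Alternatives for ODO1, the gene lists and the overlap of peaks with changed genes were not run, since no gene names or positions were used here.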

Other observations

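The tests of sequencing depth, of a few dominant genes, of matched scaffolds and of matched narrow peaks were chosen after the results were seen, as were the limits of 800 bases and 1000 CPM and the look at the strongest 100 peaks.

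Wide peaks often lay on scaffolds that carry very abundant corolla transcripts. In the 35S list 26 of 47 peaks of at least 800 bases (55.3%) lay on a scaffold with a gene averaging at least 1000 CPM, here without TMM, over the 6 RNA libraries, and in the pODO1 list 12 of 40 (30%). There were 82 such genes, on 75 scaffolds, which held 7.75% of all 35S and 7.44% of all pODO1 peaks. Counted once per scaffold, 21 of 41 scaffolds with a wide 35S peak and 10 of 30 with a wide pODO1 peak carried such a gene. With a minimum of 500 bases the percentages for 35S and pODO1 were 19.95 and 10.5, and with 1000 bases 61.5 and 31.8.

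Scaffold size and peak density are argued against by scaffolds matched on span or on number of peaks, which carried such a gene at 8.13% on average at most. The one-sided p over 10000 draws of matched scaffolds was 0.0001 in each list and matching, the smallest possible, with each scaffold counted once. Matched scaffolds carried no wide peak of the same list and were not matched on their number of genes. Strength alone is argued against by narrow peaks of matched fold enrichment, 1 drawn for each scaffold with a wide peak. These came from scaffolds without a wide peak, and 7.34% on average at most lay on scaffolds with such a gene (one-sided permutation p = 0.0001 in each list, again the smallest possible). Narrow peaks drawn from all scaffolds, 1 for each wide peak, did so at a mean of 8.10% for 35S and 7.23% for pODO1. No gene positions were used, so a wide peak may lie far from the abundant gene of its scaffold. ChIP background over strongly transcribed genes and binding by the GFP-carrying protein cannot be told apart. At least 95% of the wide peaks of each list were overlapped in the other, which both predict, and no list from plants without GFP was used here.

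Wild type replicate 4 had 12.1% of its counts on its 1217 raised genes, against at most 2.96% in any other library. Sequencing depth is argued against by thinning all libraries to its total, the lowest of the 6: among genes with a mean of at least 100 counts in the other 5 libraries it was still over 2-fold above every other library at 526, while no other library was at more than 46 by the same rule. The smaller share of its 10 most counted IDs can raise other genes by 1.03-fold at most, which argues against a few dominant genes. If this library were an odo1i sample wrongly labelled wild type, it would lie nearer to the odo1i mean at most of the 435 genes called without it. It lay nearer to the wild type mean at 65.1% of them, which argues against such a wrong label only weakly. Over the 200 genes of smallest p it was nearer to its own group at 67.5%, against 80.5% to 98% for the other libraries. On the second principal component of log2 CPM (24.1% of variance) it lay at -25.3. There the odo1i libraries lay at -55.0 to -1.21, and wild type replicates 1 and 2 at 60.9 and 50.5. Flower stage, harvest time, plant line or another tissue may differ in this library and were not tested, since no marker gene could be named.

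Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many calls, the real split with 111, and the highest of the others gave 0. The splits are too few for a share under 0.05.

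A hypothesis was that genes lower in odo1i lie on scaffolds dense in shared peaks, tested on scaffolds spanning at least 100000 bases. The 44 placed genes that fell had a mean of 3.06 pODO1 peaks shared with 35S per 100 kb of scaffold, against 2.83 (middle 95% from 2.49 to 3.19) in 10000 random sets of tested genes matched on expression (two-sided permutation p = 0.206, adjusted over 3 sets 0.497). The 64 placed genes that rose had 2.72 against 2.86 (two-sided permutation p = 0.331, adjusted 0.497), and all 108 had 2.86 against 2.85 (two-sided permutation p = 0.958, adjusted 0.958). It had been set in advance that a mean inside the middle 95% would speak against binding near the changed genes. That was wrong for this measure, because 1 more shared peak for each of the 44 genes would raise their mean by 0.115, while the upper end of the middle 95% lies 0.366 above the random mean. The question stays open.

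The strongest peaks lay more often on scaffolds without a gene ID. Of the 100 peaks of highest fold enrichment, 46 pODO1 and 36 35S peaks did so, against 9.23% and 9.30% of all peaks. On scaffolds whose last peak ended before 10000 bases lay 44 and 36 of them, against 6.31% and 6.76% of all peaks.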
